A study of Homo sapiens with 6 samples.

How the data were processed

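RNA of T24 cells, an established human bladder cancer line, was hybridised to 6 single-colour oligonucleotide arrays, 3 from cells given vehicle and 3 from cells given ox-LDL at 20 µg/mL for 24 h. Per the labels' protocols, cells were grown in medium with 10% serum and kept without serum for 12 h before treatment, total RNA was extracted with Trizol, and biotinylated single-stranded cDNA was made from 500 ng of RNA with an Affymetrix WT PLUS kit. The authors deposited log2 expression values made with RMA (robust multi-array average), per the submitters' processing notes. RMA as generally defined corrects background, makes the distribution of probe values equal across arrays and summarises the probes of a probe set by median polish; its version and settings, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. The log2 scale was read from the values, which ran from 2.28 to 14.1. Because RMA equalises arrays, a change of total RNA per cell cannot be seen in such values, and it pulls values near the background together, so changes of dim genes are understated. Scanner files were not used here, and neither scan date nor batch is given in the sources used here.

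The value table held 24350 probe sets. The 2902 control probe sets (612 negative controls, 2197 positive controls, 63 spike-in controls and 30 others) were left out of the tests, which left 21448. A table of platform annotation gave exactly 1 gene symbol for 17709 of these, several for 0 and none for 3739, which are unnamed here. All 17709 gene numbers were found in the reference gene table and 0 symbols had to be updated. These probe sets stood for 17687 genes, of which 20 had several probe sets and were represented in list tests by the one with the highest mean. The 95th percentile of the negative control values was 5.09, and 20.2% of the tested probe sets lay at or below it in both groups; they were kept, and named genes among them are said to lie there. For arrays no depth applies, and the number of arrays limits the precision.

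Samples were grouped by their titles, whose groups the source, treatment and protocol labels also give. A description label that speaks of control and G9a siRNA contradicts these, and the level of EHMT2, which encodes G9a, was read as a check on it. All 6 arrays entered one limma model (lmFit and eBayes, limma 3.58.1 in R 4.3.3; figures with matplotlib 3.10.9) of ox-LDL minus vehicle, with two-sided p-values adjusted by the Benjamini-Hochberg method over 21448 probe sets and called under 0.05. The study's design text gives a selection of p at or below 0.001 and a fold change of at least 1.5, without naming a test or an adjustment; it was applied to the unadjusted limma p. A fold change is 2 to the power of the difference of group means of log2 values. Errors are SD over arrays of a group or limma's standard error of a difference, and intervals are 95% confidence intervals from the same model.

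Before the data were examined, 34 gene lists were fixed from general knowledge: 7 primary lists (SREBP2, LXR and NRF2 targets, NF-kB and inflammatory cytokines, the JAK-STAT3 pathway, stemness markers and epithelial-mesenchymal transition) and others for stress responses, cell cycle, metabolism, urothelial identity, other cell types and RNA quality. The 32 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list with all other genes, and adjusted over the 32. Camera with an estimated correlation and fry, a rotation test of the list by itself, were alternatives. Members are counted at the adjusted p over all probe sets, and also adjusted over the list alone.

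Genes are named by a rule fixed beforehand: 13 genes whatever their values, of which 11 are reported (EHMT2, CD36, OLR1, ABCA1, ABCG1, HMOX1, PLIN2, JAK2, STAT3, CD44 and SOX2), the 10 largest rises and 10 largest falls among passing genes whose arrays of 1 group all lie above those of the other, and the 4 members of each list with the smallest p. Genes named otherwise are said to be chosen after their values were seen. The other 2 of the 13 are not reported here.

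Alternatives fixed beforehand were equal array medians, a second quantile normalization, cyclic loess, keeping only probe sets above the median level, an intensity trend with a robust fit, array weights, an ordinary unmoderated t statistic, the replicate number as a block, other thresholds, 1 probe set per named gene, the mean of a gene's probe sets, and leaving out each array in turn. The procedure was tested on simulated data of 21448 probe sets in which 200 were changed: of 100 changed 1.5-fold, 30% were recovered, and of 100 changed 2-fold, 67%, with 1 false call among 98. Most changes of 1.5-fold were thus missed in the simulation. The real comparison gave 1451 calls, so the unadjusted p needed to pass was lower in the simulation. Its shares recovered therefore do not carry over to the real data.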

Results

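Gene expression was measured in T24, an established human bladder cancer cell line, after exposure to oxidized low-density lipoprotein (ox-LDL). This is a cholesterol-carrying plasma particle whose lipids and protein have been oxidized, and it is taken up by cells through scavenger receptors. Cells were deprived of serum for 12 h and then given ox-LDL at 20 µg/mL or vehicle for 24 h. Each group held 3 samples, with 1 array per sample, and the comparison asked which transcripts differed between ox-LDL and vehicle. The labels do not say that the 3 samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value. The median log2 value of an array lay between 7.11 and 7.18. The third vehicle array stood apart: its correlation with the other arrays, across probe sets, was 0.979 to 0.988, against 0.992 to 0.997 among the other 5 arrays. Its background probe sets with the most G and C bases were also brighter, at a mean log2 value of 7.94 against 7.44 to 7.53.

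**Figure D1:**
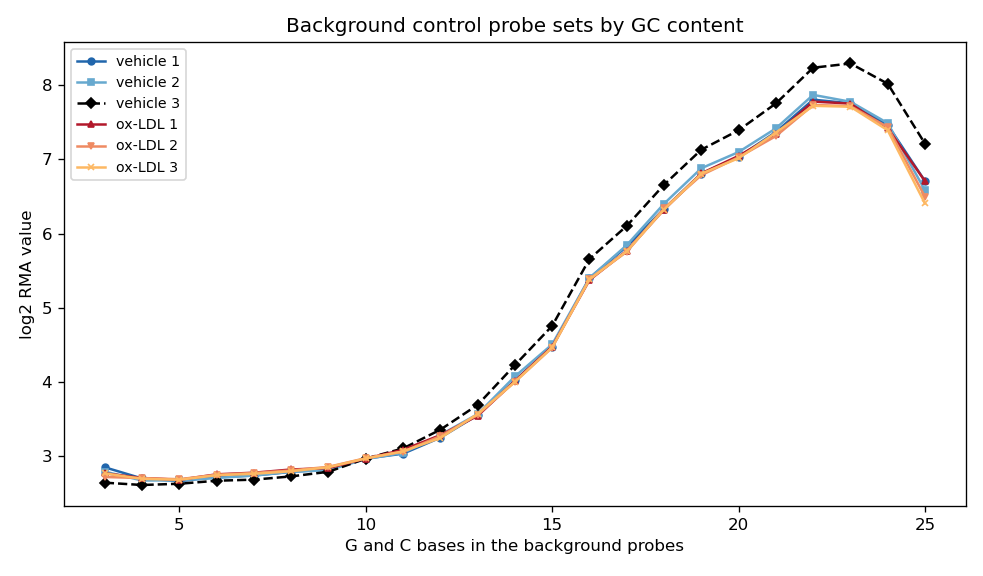
Log2 RMA value (y axis) of the background control probe sets by the number of G and C bases in their probes (x axis), with 1 line per array. Above about 12 G and C bases the dashed line of vehicle replicate 3 lies over those of the other 5 arrays, which run close together.

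One free-text label field described the same arrays as negative control siRNA and siRNA against the histone methyltransferase G9a, while titles, source, treatment and protocol fields all named vehicle and ox-LDL. Groups followed the latter fields. EHMT2, the gene that encodes G9a, had log2 values of 8.005, 7.91 and 7.63 on the vehicle arrays and 8.34, 8.26 and 8.06 on the ox-LDL arrays. Its mean was 7.85 ± 0.19 (SD, n = 3) in vehicle and 8.22 ± 0.14 (SD, n = 3) with ox-LDL. The difference of 0.37 (SE 0.12, 95% confidence interval 0.07 to 0.66) did not pass the test (limma adjusted p = 0.125). Of the 9 measured members of the G9a methyltransferase complex list, SUV39H2, another histone H3 lysine 9 methyltransferase, rose by 0.49 on the log2 scale and the other 8 did not pass, among them CBX3, CBX1 and SUV39H1 (log2 differences 0.33, 0.30 and 0.26). Adjusted over the list alone 5 were higher, and without vehicle replicate 3 there were 3 that passed over all probe sets, while SUV39H2 lost its call without either of the other vehicle arrays or without ox-LDL replicate 1 or 2. The list was higher as a group (median 0.26, camera adjusted p = 0.0169), but not with an estimated correlation (adjusted p = 0.153), after cyclic loess (adjusted p = 0.0696) or among the brighter probe sets alone (adjusted p = 0.104).

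With ox-LDL, ABCA1, the transporter that exports cellular cholesterol to apolipoprotein A-I, showed the largest rise, and PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, the largest fall among the genes that passed. ABCA1 went from a log2 value of 6.17 ± 0.09 to 8.34 ± 0.07 (SD, n = 3 each), a 4.51-fold rise (log2 difference 2.17, SE 0.08, adjusted p = 0.000159). PTGS2 went from 9.96 ± 0.38 to 5.83 ± 0.13 (SD, n = 3 each) and was 17.5-fold lower (log2 difference -4.13, SE 0.19, adjusted p = 0.00028). After ABCA1, the 9 genes with the largest rise were CD24, a small surface glycoprotein (log2 difference 1.94), EDN1, which encodes the vasoconstrictor endothelin-1 (1.90), the carboxypeptidase CPA4 (1.70), the transforming growth factor β co-receptor TGFBR3 (1.66), the guidance factor SEMA3E (1.62), the actin-binding protein TAGLN (1.56), ANKRD1 (1.50), the zinc finger gene ZSCAN31 (1.42) and the adenylate kinase AK5 (1.39). After PTGS2, the 9 largest falls were those of CSF3, which encodes granulocyte colony-stimulating factor (-2.87), the anticoagulant receptor THBD (-2.53), the iron-siderophore carrier LCN2 (-2.47), the chemokine CCL20 (-2.38), PARM1 (-2.27), the neutrophil-attracting chemokine CXCL3 (-2.13), the endoplasmic reticulum co-chaperone DNAJB9 (-2.10), the interleukin 33 receptor IL1RL1 (-1.99) and the stress-induced transcription factor DDIT3 (-1.99). The rule that chose these 20 genes required the 3 arrays of 1 group to lie above the 3 of the other. The standard errors of the 20 genes ran from 0.08 for TAGLN to 0.23 for LCN2. The ANKRD1 call was lost without any 1 ox-LDL array (adjusted p = 0.0602, 0.0661 and 0.0703), and those of ANKRD1 (adjusted p = 0.0757) and TGFBR3 (adjusted p = 0.0555) with an unmoderated t statistic. CXCL3 shares long stretches of sequence with CXCL1 and CXCL2, so its value is uncertain.

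**Figure D2:**
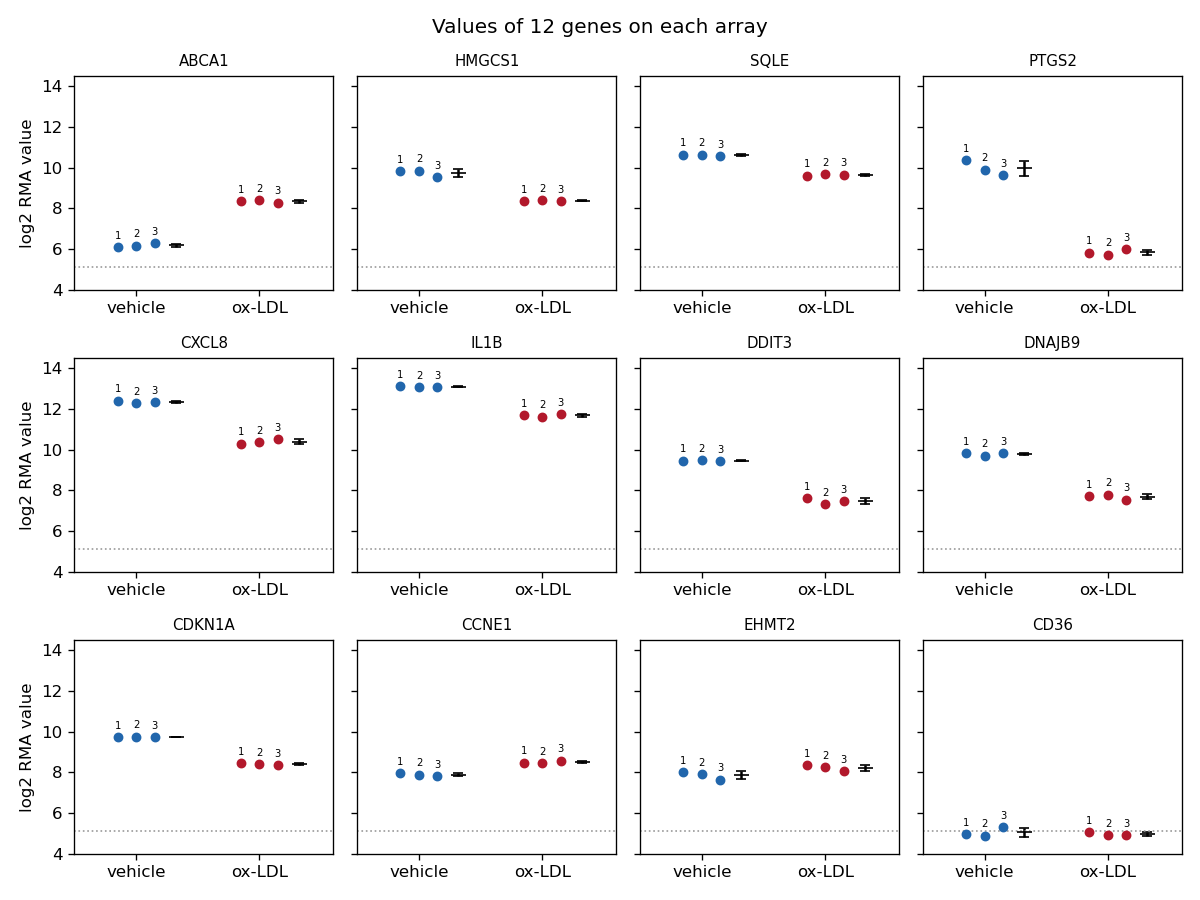
Log2 RMA values (y axis) of 12 genes on each of the 6 arrays, vehicle in blue and ox-LDL in red, with the replicate number over each point, the group mean and its SD (n = 3) as a black bar, and the 95th percentile of the negative control probe sets, 5.09, as a dotted line. ABCA1 and CCNE1 lie higher on all 3 ox-LDL arrays than on all 3 vehicle arrays. HMGCS1, SQLE, PTGS2, CXCL8, IL1B, DDIT3, DNAJB9 and CDKN1A lie lower on all 3. EHMT2 also lies higher on all 3 ox-LDL arrays but did not pass the test, and CD36 lies near the dotted line.

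Across the array, 1451 of 21448 probe sets passed the test (limma, Benjamini-Hochberg adjusted p under 0.05), 746 of them higher and 705 lower with ox-LDL. Of these, 1267 had a gene name, 655 higher and 612 lower. Falls were the larger changes: of the 134 passing probe sets that changed at least 2-fold, 89 were lower and 45 higher. The study's stated selection, p at or below 0.001 with a fold change of at least 1.5, took 496 probe sets, 215 higher and 281 lower. The count of 1451 depended on single arrays, with 2670 without vehicle replicate 3, 806 and 718 without vehicle replicates 1 and 2, and 309, 305 and 335 without ox-LDL replicates 1, 2 and 3. Without vehicle replicate 3, 1439 of the 1451 passed again, all in the same direction. The balance of rises and falls among the calls varied too: 822 higher and 602 lower with equal array medians, 683 and 731 after a second quantile normalization, 702 and 768 after cyclic loess, 1450 and 1220 without vehicle replicate 3, and 97 and 212, 93 and 212, and 106 and 229 without ox-LDL replicates 1, 2 and 3. Of the 92 genes named in the text that passed, 40 lost the call when some 1 array was left out, and none had a log2 difference that moved by over 1.5 times. Of the 72 named genes that did not pass, 15 passed without vehicle replicate 3, and 26 moved by over 1.5 times without some 1 array, 23 of them without vehicle replicate 3.

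Genes of cholesterol synthesis and regulation fell together. Of 20 measured targets of SREBP2, the transcription factor that turns on these genes when cell cholesterol is low, 17 fell and 3 did not pass, and adjusted over the list alone 19 were lower and 1 higher. HMGCS1, which makes the precursor of mevalonate, fell by 1.37 on the log2 scale (SE 0.10, adjusted p = 0.00126). SQLE, the squalene epoxidase, fell by 0.97 (SE 0.07), INSIG1, which holds SREBP proteins in the endoplasmic reticulum when sterols are plentiful, by 0.98 (SE 0.07), and the sterol oxidase MSMO1 by 0.86 (SE 0.07). The list's median log2 difference was -0.60 and its shift passed with a preset correlation (camera adjusted p = 4.45e-14) and with an estimated one (adjusted p = 0.0381). The count of lower members was 17 without vehicle replicate 3, 12 and 9 without vehicle replicates 1 and 2, and 7 without any 1 ox-LDL array.

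The targets of LXR, the receptor that responds to oxidized cholesterol derivatives, were not called as a group. Of 12 measured, ABCA1 and LPCAT3, a phospholipid-remodelling acyltransferase (log2 difference 0.69, SE 0.11), rose, SCD, the stearoyl-CoA desaturase, fell by 0.50 (SE 0.07), and 9 did not pass; adjusted over the list alone 2 were higher and 3 lower. APOC1, an apolipoprotein, had a log2 difference of -0.33 (SE 0.09, adjusted p = 0.0831). ABCG1, another cholesterol exporter, had a log2 difference of -0.09 (SE 0.09, adjusted p = 0.524) and lay at or below the 95th percentile of the negative controls in both groups. The list's median (-0.11, or -0.05 without vehicle replicate 3) and camera (adjusted p = 0.583, or 0.972 without it) pointed down, while its mean (0.09) and the rotation test fry pointed up (adjusted p = 0.210). LPCAT3 and SCD lost their calls without any 1 ox-LDL array, which left ABCA1 as the member that passed.

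Inflammatory transcripts fell most. Of 21 measured NF-kB targets and cytokines, 17 fell and 4 did not pass, and 19 were lower when adjusted over the list alone. CXCL8, which encodes interleukin 8, fell by 1.97 on the log2 scale (SE 0.09, adjusted p = 0.00026), from 12.35 ± 0.06 to 10.38 ± 0.12 (SD, n = 3 each). IL1B, which encodes interleukin 1β, fell by 1.42 (SE 0.07) from 13.09 ± 0.03 to 11.67 ± 0.06 (SD, n = 3 each), and PTGS2 and CXCL3 had the log2 differences of -4.13 and -2.13 given above. The median of the list was -1.02, the most negative of the 32 lists tested (camera adjusted p = 1.1e-20, or adjusted p = 0.0429 with an estimated correlation). With 1 array left out, between 15 and 17 members were lower.

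Genes of the integrated stress response were lower as well. Of 21 targets of ATF4, its transcription factor, 16 fell and 5 did not pass (median -0.68, camera adjusted p = 1.01e-14, adjusted p = 0.0429 with an estimated correlation); adjusted over the list alone 18 were lower and 1 higher. DDIT3, the pro-apoptotic factor also called CHOP, fell by 1.99 (SE 0.09), the pseudokinase TRIB3 by 1.59 (SE 0.07), SESN2, an inhibitor of mTORC1 signalling, by 1.25 (SE 0.09), and the phosphatase subunit PPP1R15A, which ends the stress response, by 1.19 (SE 0.10). The count of lower members was 9 without ox-LDL replicate 1 or 2 and 10 without ox-LDL replicate 3, against 13 to 17 without a vehicle array.

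Of 16 genes of the endoplasmic reticulum unfolded protein response, 9 fell and 7 did not pass (median -0.40, camera adjusted p = 3.5e-07), and adjusted over the list alone 12 were lower and 1 higher. The list's shift did not pass with an estimated correlation (adjusted p = 0.153). DNAJB9 fell by 2.10 (SE 0.09), HERPUD1, a factor of protein degradation at that membrane, by 1.34 (SE 0.07), and the chaperones HSPA5 and HYOU1 by 0.71 (SE 0.07) and 0.60 (SE 0.07). The lower members numbered 11 without vehicle replicate 3, 6 without either other vehicle array, and 5, 4 and 4 without ox-LDL replicates 1, 2 and 3. The heat shock genes, a separate chaperone response, had 11 members measured and none passed in limma, against 3 at an unadjusted p under 0.05 and 1 by an unmoderated t statistic (camera adjusted p = 0.0686, or 0.0376 without vehicle replicate 3 and 0.0170 with an intensity trend and robust fit; fry passed upward, adjusted p = 0.00178). Its 4 members with the smallest p had log2 differences of -0.24 for BAG3, 0.56 for HSPE1, 0.16 for HSPA1A and 0.17 for DNAJB1. Without vehicle replicate 3 HSPE1 (0.37) rose and BAG3 (-0.27) fell past the threshold. HSPA1A is nearly identical to HSPA1B, so its value is uncertain.

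Metallothioneins, small proteins that bind zinc and copper, and the zinc exporter listed with them fell in 8 of 9 measured members over all probe sets and when adjusted over the list alone (median -0.43, camera adjusted p = 6.86e-07, adjusted p = 0.0429 with an estimated correlation). MT1F fell by 0.55 (SE 0.07), MT1H by 0.53 (SE 0.07), MT1G by 0.48 (SE 0.07) and MT1B by 0.43 (SE 0.07). These genes are near-identical copies whose probe sets can read each other's transcripts, so the 8 values are not separate evidence. The number that passed was 8 without vehicle replicate 3, 4 and 3 without vehicle replicates 1 and 2, and 0 without any 1 ox-LDL array.

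Of 18 autophagy and lysosome genes, 6 fell and 12 did not pass, and adjusted over the list alone 8 were lower and 1 higher (median -0.17, camera adjusted p = 0.00161, adjusted p = 0.153 with an estimated correlation). WIPI1, a phosphoinositide-binding autophagy protein, fell by 1.23 (SE 0.08), the cargo receptor SQSTM1 by 0.89 (SE 0.08), MAP1LC3B, which marks autophagosome membranes, by 0.74 (SE 0.07), and NPC1, which moves cholesterol out of lysosomes, by 0.47 (SE 0.07). Without any 1 ox-LDL array 3 were lower, and NPC1 was not among them.

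**Figure D3:**
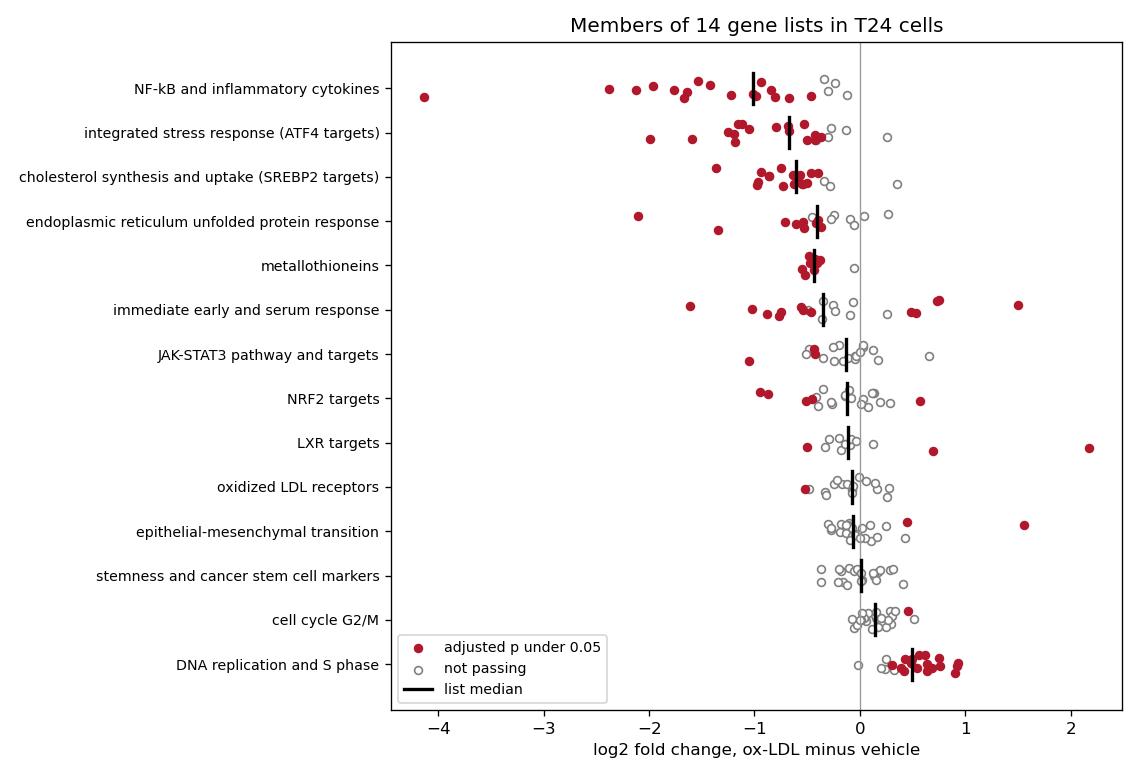
Log2 fold change, ox-LDL minus vehicle (x axis), of each measured member of 14 gene lists (y axis; spread within a row only separates the points). Filled points passed at an adjusted p under 0.05, open points did not, and black bars are list medians, which run from -1.02 for the inflammatory list to 0.49 for the DNA replication list.

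Genes of DNA replication and S phase rose. Of 23 measured, 17 rose and 6 did not pass, and 22 were higher when adjusted over the list alone. E2F1, the transcription factor of S phase entry, rose by 0.64 (SE 0.07, adjusted p = 0.00554), CCNE1, which encodes cyclin E1, by 0.62 (SE 0.08), the helicase subunit MCM3 by 0.64 (SE 0.09) and the replication factor GINS1 by 0.56 (SE 0.08). The list's median was 0.49 (camera adjusted p = 1.54e-14), but its shift did not pass with an estimated correlation (adjusted p = 0.107). Without vehicle replicate 3, 21 rose, and 11 and 10 did without vehicle replicates 1 and 2, against 2, 2 and 3 without ox-LDL replicates 1, 2 and 3, where MCM3 and GINS1 did not pass.

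Of 24 genes of G2 and mitosis, CDK1, the mitotic kinase, rose by 0.46 (SE 0.09, adjusted p = 0.0324) and 23 did not pass, while 5 were higher when adjusted over the list alone. NUSAP1, BUB1B and KIF20A, all mitotic genes, had log2 differences of 0.29, 0.30 and 0.52 (adjusted p = 0.0536, 0.0568 and 0.0633). The list was higher as a group (median 0.15, or 0.09 without vehicle replicate 3; camera adjusted p = 0.00161), but not with an estimated correlation (adjusted p = 0.279). Without vehicle replicate 3, 4 members rose, and CDK1 did not pass without vehicle replicate 2 or any 1 ox-LDL array. Among 13 measured p53 targets, CDKN1A, which encodes the cell cycle inhibitor p21, fell by 1.35 (SE 0.07, adjusted p = 0.000369), the growth arrest gene GADD45A by 0.66 (SE 0.07) and the death receptor TNFRSF10B by 0.59 (SE 0.07), and 10 did not pass, among them SESN1 (log2 difference 0.36, SE 0.11). Adjusted over the list alone 6 were lower and 3 higher. The p53 list as a group did not pass (camera adjusted p = 0.0972) but did without vehicle replicate 3, where 5 members fell (adjusted p = 0.0276), after a second quantile normalization (0.0236) or cyclic loess (0.0183), among the brighter probe sets (0.0103), with an intensity trend (0.0435), with array weights (0.0270) and in fry (0.00178), with up to 0.255 over the other alternatives. TNFRSF10B lost its call without ox-LDL replicate 2.

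For the JAK-STAT3 pathway, 3 of 20 measured members fell and 17 did not pass, with 7 lower when adjusted over the list alone. CEBPB, a transcription factor of cytokine and stress responses, fell by 1.05 (SE 0.09, adjusted p = 0.00239), FOSL1, a subunit of AP-1, by 0.42 (SE 0.08) and IL6ST, the shared receptor subunit of interleukin 6 cytokines, by 0.43 (SE 0.09). The kinase PIM3 had a log2 difference of -0.35 (adjusted p = 0.0533). JAK2 had a log2 difference of 0.00 (SE 0.13, adjusted p = 0.994), with a sign that turned under array weights, and STAT3 one of -0.11 (SE 0.07, adjusted p = 0.336). The list was lower as a group (median -0.13, camera adjusted p = 0.0138), but not with an estimated correlation (adjusted p = 0.153) or without vehicle replicate 1 (adjusted p = 0.0512). Without vehicle replicate 3, 5 members fell, and 1 did without any 1 other array, where FOSL1 and IL6ST did not pass and CEBPB did. Of the 3 members that fell in the main fit, 1 also belongs to another list, so its fall is not separate evidence for this pathway.

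None of the 21 measured stemness and cancer stem cell markers passed in limma, also when adjusted over the list alone; 1 had an unadjusted p under 0.05 and 1 passed with an unmoderated t statistic. ALDH1A3 had a log2 difference of -0.18 (SE 0.07, adjusted p = 0.149), the hyaluronan receptor CD44 one of -0.16 (SE 0.07, adjusted p = 0.197), KLF4 one of -0.20 (SE 0.08) and MYC one of 0.17 (SE 0.08). SOX2 had a log2 difference of -0.06 (SE 0.13, adjusted p = 0.805; 95% confidence interval -0.37 to 0.26), and its sign turned after cyclic loess and without vehicle replicate 3. The list was not called (camera adjusted p = 0.943), and its median and mean were 0.01 and 0.00 while camera and fry pointed down.

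Of 24 genes of the epithelial-mesenchymal transition, TAGLN rose by 1.56 (SE 0.08) and SPARC, a matrix-associated glycoprotein, by 0.45 (SE 0.07, adjusted p = 0.0173), and 22 did not pass, with 3 higher when adjusted over the list alone. The cadherin gene CDH2 had a log2 difference of 0.43 (adjusted p = 0.0516, or 0.0248 without vehicle replicate 3), and the transcription factor ZEB1 one of -0.19 (adjusted p = 0.164). SPARC lost its call without vehicle replicate 1 or any 1 ox-LDL array. The list did not pass in camera (adjusted p = 0.840), where its median was negative (-0.06) and its mean (0.05) and the test positive, while fry, which asks whether the members move one way on balance without comparing them with other genes, passed upward (adjusted p = 0.00227).

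Targets of NRF2, the transcription factor of the antioxidant response, included the cystine transporter SLC7A11, which fell by 0.95 (SE 0.08, adjusted p = 0.00219), the aldo-keto reductase AKR1C1, which fell by 0.87 (SE 0.15), the heme oxygenase HMOX1, which fell by 0.51 (SE 0.10, adjusted p = 0.0289), and GCLC, which makes the precursor of glutathione and fell by 0.45 (SE 0.09). The transporter ABCC3, named here after its value was seen, rose by 0.57, and the other 17 of 22 measured did not pass; adjusted over the list alone 7 were lower and 2 higher. AKR1C1 has near-identical relatives, so its value is uncertain. The list did not pass as a group (camera adjusted p = 0.156) except after cyclic loess (adjusted p = 0.0438) and without vehicle replicate 3 (adjusted p = 0.0328), where 8 members fell, with adjusted p up to 0.534 over all alternatives. HMOX1 and GCLC lost their calls when any 1 array other than vehicle replicate 3 was left out. AKR1C1 and ABCC3 lost theirs without vehicle replicate 2 or any 1 ox-LDL array. Lower members numbered 2 without vehicle replicate 1 and 1 without vehicle replicate 2 or any 1 ox-LDL array.

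The receptors that can take up ox-LDL gave few passing changes. Of 17 measured, VLDLR, a lipoprotein receptor, fell by 0.52 (SE 0.11, adjusted p = 0.0363), over all probe sets and when adjusted over the list alone, and 16 did not pass (camera adjusted p = 0.377). VLDLR lost its call when any 1 array other than vehicle replicate 3 was left out. CD36, the class B scavenger receptor, had log2 values of 5.03 ± 0.22 in vehicle and 4.96 ± 0.08 with ox-LDL (SD, n = 3 each; difference -0.07, SE 0.12, adjusted p = 0.729), and OLR1, the lectin-like ox-LDL receptor, 4.59 ± 0.12 and 4.53 ± 0.23 (difference -0.06, SE 0.13, adjusted p = 0.780). The means of both genes lay at or below the 95th percentile of the negative controls in both groups, 5.09, so a fall in them could hardly be seen on these arrays. The 95% confidence intervals were -0.36 to 0.22 for CD36 and -0.37 to 0.25 for OLR1. The sign of each turned after cyclic loess. SCARB1, TLR2 and STAB2 had log2 differences of 0.25, -0.33 and -0.49 (adjusted p = 0.131, 0.154 and 0.160), and STAB2 had -0.31 without vehicle replicate 3. Without that array 2 members were lower, as TLR2 passed (-0.47, adjusted p = 0.0104).

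Among 17 genes of lipid droplets and PPAR signalling, CPT1A, which admits fatty acids to mitochondria, rose by 0.88 (SE 0.08, adjusted p = 0.00226) and the mitochondrial carnitine carrier SLC25A20 by 0.56 (SE 0.10), and 15 did not pass. Adjusted over the list alone 3 were higher and 1 lower. PLIN2, the lipid droplet coat protein, had log2 values of 8.68 ± 0.18 and 8.74 ± 0.07 (SD, n = 3 each; difference 0.06, SE 0.11, adjusted p = 0.744). The fatty acid binding protein genes FABP5 and FABP4 had log2 differences of 0.50 and -0.50 (adjusted p = 0.0570 and 0.0841), with FABP4 at or below the negative control level in both groups. FABP5 passed without vehicle replicate 3 (0.38, adjusted p = 0.0329). The list did not pass (camera adjusted p = 0.239). SLC25A20 was not among the passing members without vehicle replicate 2 or any 1 ox-LDL array, where 1 member rose.

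Immediate early and serum response genes split. Of 21 measured, 8 fell, 5 rose and 8 did not pass, and adjusted over the list alone 12 were lower and 6 higher. EGR1, a growth-factor-induced transcription factor, fell by 1.62 (SE 0.10, adjusted p = 0.000671), PHLDA1 by 1.02 (SE 0.07), IER3 by 0.88 (SE 0.07) and the phosphatase DUSP5 by 0.75 (SE 0.07). The 5 that rose were ANKRD1 (1.50) and, named here after their values were seen, CCN2 (0.75), CCN1 (0.73), DUSP4 (0.53) and JUN (0.49). The list was lower as a group (median -0.35, camera adjusted p = 0.0161), but not with an estimated correlation (adjusted p = 0.196) or without vehicle replicate 1 (adjusted p = 0.0512). Without any 1 ox-LDL array 5 fell and 1 or 2 rose, and 3 rose without vehicle replicate 2. JUN lost its call when any 1 array other than vehicle replicate 3 was left out, DUSP4 without vehicle replicate 2 or any 1 ox-LDL array, and CCN2 without ox-LDL replicate 1 or 2.

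Of 15 iron and ferroptosis genes, 5 fell and 1 rose, and so did 5 and 1 when adjusted over the list alone, but all 6 also belong to other lists. The 5 were PTGS2, SLC7A11, HMOX1, the glutathione-degrading enzyme CHAC1 (log2 difference -1.12) and the amino acid transporter subunit SLC3A2 (-0.43); the transferrin receptor TFRC, named after its value was seen, rose by 0.38. The list was lower (median -0.19, or -0.08 without vehicle replicate 3; camera adjusted p = 0.0220) but not with an estimated correlation (adjusted p = 0.153). Without any 1 ox-LDL array 3 were lower, SLC3A2 and HMOX1 not among them, and TFRC lost its call when any 1 array other than vehicle replicate 3 was left out, with an unmoderated t statistic (adjusted p = 0.0519) and with the replicate block (0.105). Of 20 genes of oxidative phosphorylation, SDHA, a subunit of succinate dehydrogenase, rose by 0.35 and 19 did not pass. None passed when adjusted over the list alone. The oxidative phosphorylation list was higher (median 0.19, camera adjusted p = 0.000108), also without vehicle replicate 3 (median 0.14, camera adjusted p = 0.000233). It was not with an estimated correlation (adjusted p = 0.153). SDHC, NDUFB5 and CYC1 had log2 differences of 0.30, 0.25 and 0.22. SDHA lost its call when any 1 array other than vehicle replicate 3 was left out, after a second quantile normalization (adjusted p = 0.0698) or cyclic loess (0.0728), with an unmoderated t statistic (0.0633) and with the replicate block (0.122). Of 23 genes of hypoxia and glycolysis, NDRG1, a hypoxia-induced gene, fell by 1.07 (SE 0.08), the glucose transporter SLC2A3 by 0.57 and the aldolase ALDOC by 0.51, the peptide hormone gene ADM rose by 0.61, and 19 did not pass (camera adjusted p = 0.118, or 0.0456 with an intensity trend and robust fit; fry passed upward, adjusted p = 0.00202). Adjusted over the list alone 2 were higher and 3 lower. ADM and SLC2A3 lost their calls without any 1 ox-LDL array. ALDOC lost its call without vehicle replicate 1 or 2 or ox-LDL replicate 1 or 2.

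Of 21 interferon response genes, BST2, which tethers budding viruses, rose by 0.64 and IRF9, a factor of interferon signalling, fell by 0.37, and 19 did not pass, among them OAS2 and IRF7 (log2 differences 0.64 and -0.31; camera adjusted p = 0.156); adjusted over the list alone 2 were higher and 1 lower. Both calls were absent when any 1 array other than vehicle replicate 3 was left out. Of 14 luminal urothelial markers XBP1 fell by 0.54 while ERBB3, KRT7 and UPK3B had log2 differences of 0.87, 0.28 and -0.35 and did not pass (camera adjusted p = 0.583), and of 13 basal and squamous markers the protease inhibitor gene PI3 fell by 0.59 while DSG3, which lay at or below the negative control level in both groups, DSC3 and EGFR had log2 differences of 0.22, 0.23 and -0.18 and did not pass (camera adjusted p = 0.291). Adjusted over the list alone these were 1 lower and 2 higher for the luminal list and 1 lower for the basal one. Without vehicle replicate 3, ERBB3 (0.97, adjusted p = 0.0479) and KRT7 (0.32, adjusted p = 0.0290) of the luminal list and DSG3 (0.26, adjusted p = 0.0377) of the basal list rose. XBP1 also belongs to another list, so its fall is not particular to the luminal markers. It lost its call without ox-LDL replicate 2 or 3, and PI3 lost its call without vehicle replicate 2 or any 1 ox-LDL array.

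No marker of another cell type passed in limma among 14 leukocyte, 11 endothelial, 9 fibroblast and mural, and 6 erythroid markers, of which 2, 2, 2 and 1 had an unadjusted p under 0.05 and none passed with an unmoderated t statistic. Adjusted over the list alone, 1 erythroid marker was lower. Camera gave adjusted p of 0.212 for the leukocyte, 0.239 for the endothelial, 0.377 for the fibroblast and 0.377 for the erythroid list. The members with the smallest p had log2 differences of -0.32 for TYROBP, -0.36 for CD14, -0.26 for CD79A and -0.38 for ITGAM among leukocyte markers. Among endothelial ones they were -0.30 for VWF, -0.34 for EMCN, -0.39 for CLDN5 and -0.32 for PECAM1. Among fibroblast ones they were -0.32 for DCN, 0.23 for FAP, -0.32 for COL1A1 and -0.32 for COL1A2. Among erythroid ones they were -0.39 for HBB, 0.23 for ALAS2, -0.22 for HBA2 and -0.12 for HBA1. Many of these differences rested on vehicle replicate 3. Without it they were -0.23 for CD14, -0.13 for CD79A, -0.13 for ITGAM, -0.16 for CLDN5, -0.13 for PECAM1, -0.21 for DCN, -0.14 for COL1A1, -0.11 for COL1A2, -0.11 for HBA2 and -0.03 for HBA1. ALAS2 had 0.11 without ox-LDL replicate 1. EMCN and FAP lay at or below the negative control level in both groups, and HBA1 and HBA2 are near-identical, so their values are uncertain. For signs of RNA quality, none of 18 replication-dependent histone genes passed in limma (2 at an unadjusted p under 0.05, none with an unmoderated t statistic; camera adjusted p = 0.785; log2 differences -0.23 for H2AC8, -0.20 for H1-3, 0.42 (0.18 without vehicle replicate 3) for H3C2 and -0.12 for H4C2), and 1 of 51 cytosolic ribosomal protein genes, RPL26L1, rose by 0.43, with 0.19 for RPS26, 0.34 (0.17 without vehicle replicate 3) for RPL7L1 and 0.17 for RPL24, which did not pass. The ribosomal list was slightly higher (median 0.06, or 0.04 without vehicle replicate 3; camera adjusted p = 0.00660, or 0.0455 without it), but not with an estimated correlation (adjusted p = 0.534), after cyclic loess (adjusted p = 0.135), among the brighter probe sets (adjusted p = 0.126) or with array weights (adjusted p = 0.0644). Of 11 housekeeping genes TFRC and SDHA rose, HPRT1 and ACTB had log2 differences of 0.70 and 0.27 and did not pass (adjusted p = 0.0709 and 0.0934, or 0.00694 and 0.0186 without vehicle replicate 3, where 4 members rose), and 4 were higher when adjusted over the list alone (median 0.11, or 0.06 without vehicle replicate 3; camera adjusted p = 0.00660, adjusted p = 0.224 with an estimated correlation and 0.0613 among the brighter probe sets). RPL26L1 lost its call without vehicle replicate 1 or any 1 ox-LDL array, and no housekeeping gene or SNORD52 passed when any 1 array other than vehicle replicate 3 was left out. Of the 2 small nucleolar RNAs measured, SNORD52 fell by 0.45 and SNORD89 had a log2 difference of -0.05, and the list was too short to test. Genes encoded in mitochondria were not analysed here.

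Of the 32 lists tested, 15 were called, 9 lower and 6 higher. The calls that held with an estimated correlation were the 4 of the SREBP2, NF-kB, ATF4 and metallothionein lists, all lower. No control probe set passed in limma among 612 negative, 2197 positive, 63 spike-in and 30 other controls. Of these, 65, 431, 6 and 0 had an unadjusted p under 0.05. For the negative and positive controls this was more than an even spread of p-values would give. The largest absolute log2 difference was 2.70 among the negative and 1.87 among the positive controls.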

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

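The rises and falls of the 20 leading genes and the falls of the SREBP2, NF-kB, ATF4 and metallothionein lists kept their direction under every alternative, and the 4 lists stayed past the threshold in all 16 alternatives run for each (highest adjusted p 0.0381 for SREBP2 and 0.0429 for the other 3). Of the 20 genes only ANKRD1 and TGFBR3 lost a call in some alternative. Of the 92 named genes that passed, 40 lost the call when some 1 array was left out, 21 under another alternative and 27 with the replicate block, and 0 changed direction. Of the 72 named genes that did not pass, 27 passed with array weights, 25 with an intensity trend and robust fit, 20 among the brighter probe sets, 7 with an ordinary t statistic and 15 without vehicle replicate 3. EHMT2 stayed above vehicle and short of the threshold in all 14 alternatives (adjusted p 0.0622 to 0.320).

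The count of 1451 probe sets became 2608 among the brighter probe sets, 2649 with an intensity trend and robust fit, 3962 with array weights and 598 when a fold change of at least 1.5 was also asked. It ran from 305 to 2670 when 1 array was left out, lowest without ox-LDL replicate 2 and highest without vehicle replicate 3. Fewer samples are part of the lower counts, and array weights gave vehicle replicate 3 a weight of 0.149; other causes were not tested. The study's selection of 496 became 270 with an ordinary t statistic and 33 when the p at or below 0.001 was adjusted. Same-numbered arrays did not deviate together (correlations of -0.01, 0.03 and 0.02 across probe sets). These correlations cannot tell whether the numbers pair the samples, because the outlying vehicle replicate 3 enters the deviations of all vehicle arrays. With the replicate number as a block 550 probe sets passed, 244 higher and 306 lower. The stemness list then turned upward (camera adjusted p = 0.929) with no list call changed.

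Of the 15 lists called, 4 were called with an estimated correlation, under which the JAK-STAT3 list had adjusted p = 0.153. Leaving out 1 array gave an adjusted p from 0.00238 to 0.0512 for JAK-STAT3 (highest without vehicle replicate 1) and from 0.0328 to 0.301 for NRF2 (lowest without vehicle replicate 3), and NRF2 had 0.0438 after cyclic loess. Calls of lists that were not primary changed under a second quantile normalization, cyclic loess, the brighter probe sets, the trend, array weights, fry and single arrays. Directions turned for lists that never passed in camera. LXR pointed up in fry (adjusted p = 0.210). Stemness pointed up after a second quantile normalization (0.722), after cyclic loess (0.733), among the brighter probe sets (0.991) and with array weights (0.958), with 0.915 to 0.972 when 1 array was left out. Epithelial-mesenchymal transition pointed down after cyclic loess (0.952), among the brighter probe sets (0.950) and with array weights (0.957), with 0.725 to 0.972 when 1 array was left out, and passed upward in fry (0.00227). The ox-LDL receptors (0.950) and luminal markers (0.991) pointed up among the brighter probe sets, and the histones turned when 1 array was left out (0.470 to 0.953). The cause was not tested in these cases.

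Genes that did not pass also changed sign. CD36 had log2 differences of 0.015 after a second quantile normalization, 0.026 after cyclic loess and 0.053 with array weights, and from -0.15 to 0.054 when 1 array was left out. OLR1 had 0.0098 and 0.022 after the 2 normalizations and -0.15 to 0.066 over the left-out arrays, SOX2 had 0.023, 0.052 and, with array weights, 0.021, and -0.16 to 0.046 over the left-out arrays, and ABCG1 had 0.0014 after cyclic loess. JAK2 had -0.044 with array weights and -0.11 to 0.12, and PLIN2 -0.04 to 0.12, when 1 array was left out; ACTA2 had 0.0088 after cyclic loess, 0.074 with array weights and -0.12 to 0.097 over the left-out arrays. The cause was not tested. CD36, OLR1 and ABCG1 lay at or below the negative control level, so signal over background limits them. Dim genes, and the leukocyte, endothelial, fibroblast and erythroid lists, gave no value among the brighter probe sets because too few members remained.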

Other observations

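Of the tests in this part, those of the S phase against the mitotic genes, of the label conflict, of vehicle replicate 3 and of the lower lists were chosen after the results were seen. Some of the genes that rose are linked to the actin cytoskeleton and to its transcriptional regulators SRF and YAP. Beyond TAGLN and ANKRD1, the matrix glycoprotein THBS1 (log2 difference 1.25, SE 0.09), the actomyosin regulators CALD1 (1.10, SE 0.10) and NEXN (1.08, SE 0.09) and the secreted factors CCN2 (0.75) and CCN1 (0.73) rose, all chosen after their values were seen, while the smooth muscle actin gene ACTA2 had -0.05 (SE 0.13, adjusted p = 0.835). A hypothesis is that SRF and YAP targets rose as a group, and it was tested on 21 measured targets written down without these 8 genes. Of the 21, 9 rose and 12 did not pass (median 0.28), among the latter the smooth muscle genes ACTG2 (-0.39, SE 0.15, or -0.21 without vehicle replicate 3) and CNN1 (-0.35, SE 0.15, or -0.23 without it), named like the next 4 after their values were seen. The 4 rises with the smallest adjusted p, which are not the 4 largest, were those of F3, which encodes tissue factor (0.81, SE 0.07), CRIM1 (0.54, SE 0.07), CNN2, an actin-binding calponin (0.49, SE 0.08), and the tropomyosin TPM1 (0.51, SE 0.08). Camera gave p = 2.24e-06 (p = 0.0307 with an estimated correlation, p = 1.14e-06 to 4.25e-05 when 1 array was left out, and with an estimated correlation then p = 0.0129 to 0.0849), so the rise may extend beyond the genes first noticed, though the list was conceived on the same data. The members that passed numbered 12 without vehicle replicate 3, and 5 and 3 without vehicle replicates 1 and 2. Without any 1 ox-LDL array 1 passed, and CRIM1, CNN2 and TPM1 did not. By contrast, the immediate early and serum response list was lower as a group (8 fell and 5 rose, camera adjusted p = 0.0161). EGR1 fell there by 1.62, while ANKRD1, CCN2 and CCN1 were among its rises. The 21 targets therefore do not stand for SRF targets as a whole.

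The S phase list stood higher relative to the G2 and mitosis list on the ox-LDL arrays. The mean of the S phase list minus that of the G2 and mitosis list was -1.03 ± 0.03 (SD, n = 3) in vehicle and -0.67 ± 0.01 (SD, n = 3) with ox-LDL, a difference of 0.36 on the log2 scale. The 3 ox-LDL arrays all lay above the 3 vehicle arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give).

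One label field speaks of G9a siRNA where the others speak of ox-LDL. A knockdown of G9a needs a lower EHMT2, and the lower bound of the 95% confidence interval of its log2 difference was 0.0747, above 0, which argues against it. A load of lipoprotein cholesterol would lower SREBP2 targets and raise ABCA1. Of 20 targets 17 fell, and ABCA1 rose 4.51-fold, so these genes go with the titles. Other lipid genes did so less: of 12 LXR targets 2 rose and 1 fell, and the list was not called (camera adjusted p = 0.583). PLIN2 had a log2 difference of 0.06, and HMOX1, an NRF2 target, fell by 0.51. The values of EHMT2, ABCA1 and the SREBP2 targets had been seen before the test was set. A mixed-up description field remains a candidate explanation.

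Vehicle replicate 3 stood apart, with a relative log expression spread (interquartile range) of 0.399 against 0.150 to 0.169 on the other 5 arrays and a score of 44.6 on the first principal component (60.8% of the variance), where the other 5 scored -20.3 to 7.33. A swap with an ox-LDL sample needs its deviation from vehicle replicate 1 to point along the ox-LDL response, and the correlation across probe sets was -0.17, which argues against it. A difference of labelling, hybridization or background of that array could account for it, since its background probe sets with 20 to 24 G and C bases had a mean of 7.94, above the 7.44 to 7.53 of the other 5. No biological explanation was tested.

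The inflammatory, ATF4 and SREBP2 lists were lower with ox-LDL. The outlying array as their source is argued against, since without it all 3 kept their calls (highest camera adjusted p = 1.53e-13). Leukocytes among the vehicle cells as the main source of the lower cytokine transcripts are argued against by the design, since T24 is an established cancer line. The levels of abundant leukocyte transcripts also argue against leukocytes. Such cells bring their abundant transcripts, yet PTPRC, LYZ, FCER1G and AIF1 had log2 values of 4.19, 4.14, 4.21 and 3.38 in vehicle, below the 95th percentile of the negative controls there (5.08), where IL1B had 13.09. Of 14 leukocyte markers 7 lay above that level, TYROBP highest at 8.01. These 7 all had a lower mean with ox-LDL, with a median log2 difference of -0.26, or -0.13 without vehicle replicate 3. On the linear scale the 14 markers lost a median signal of 1.81 units from vehicle to ox-LDL. The largest loss at the bound of a 95% confidence interval was 85.7. The 17 lower members of the inflammatory list lost a median of 942 units. The smallest loss among them was 122 units, or 79.5 at its bound. This comparison cannot decide, because 7 markers lay too low to fall and probe sets differ in how strongly they read a transcript. The transcript levels alone do not exclude a small share of leukocytes. Earlier forms of the linear comparison, a count of markers above the negative controls and a median of their log2 differences, were replaced because dim markers cannot fall. A response of the cells to ox-LDL, the difference named by the design, stays open, and differences in cell density or time between the dishes were not tested.

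The 6 arrays can be split into 3 and 3 in 10 ways. The real split gave 1451 probe sets at an adjusted p under 0.05 and the highest of the others 0, so 1 split reached that count. For the study's selection the real split gave 496 and the highest of the others 3, so again 1 split reached it. The 10 splits are too few for a share under 0.05. Every other split also mixes vehicle and ox-LDL arrays in each group. The treatment difference then adds to the spread within groups, so low counts were built in and do not measure chance.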
